A study of Rattus norvegicus with 40 samples.

How the data were processed

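RNA sequencing libraries were made from microglia, the resident immune cells of the central nervous system, of 8-week-old Sprague Dawley rats. The cells were isolated from the medulla and from the C3 to C6 segments of the cervical spinal cord with an antibody against CD11b on magnetic beads, per the labels' protocols. Dams had been exposed to intermittent normoxia (21% oxygen throughout) or to intermittent hypoxia (alternating 10.5% and 21% oxygen) on gestational days 10 to 21, for 8 hours a day at 15 cycles per hour, and the offspring grew up in room air. The 40 libraries formed 8 groups of sex, exposure and region with 5 libraries each. The series design describes 1 male and 1 female from each of 5 litters per exposure, with both regions taken from them, so replicates were separate animals.

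The deposited table holds raw read counts per gene, as whole numbers, for 32883 Ensembl rat gene IDs in 40 columns, and every column was matched to a library by its label. Per the submitters' processing notes, TopHat2 2.1, HTSeq and edgeR were used with genome build rn6, and the notes give no role or order for them. The annotation release, the strand setting and the filters of the authors are not given in the sources used here, so reads of overlapping, antisense or near-identical genes may have been split or shared. The table holds 0 rows that name no gene, and 9630 IDs were at 0 in every library. No 2 libraries were identical, and the lowest chi-square per degree of freedom between 2 libraries of a group was 12.6, far above that of a library deposited in duplicate.

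The files do not pair the IDs with gene names. In the reference gene table used here, 0 of 47357 rows carried an Ensembl ID, and 0 of the 32883 IDs could be matched. The tests of the 28 gene lists fixed before the data were examined, the checks on named sex-linked and cell type marker genes, and all checks of gene length or GC content were therefore not run. The fixed rule for named genes took, per comparison, the highest and lowest log2 fold changes among called genes with a symbol and an average log2 CPM of at least 1. Without symbols it named no gene, and its order was used to print 2 IDs that rose and 2 that fell in the comparison of the female cord by exposure.

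Differences were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, on the deposited counts with TMM factors, after filterByExpr by group with its minimum count of 10. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Exposure, sex and their interaction were tested among the 20 libraries of a region, which share an estimate of the spread (14151 genes in the medulla and 13593 in the cord). Region and the interactions with region were tested among all 40 libraries (14832 genes). The 17 comparisons and their alternatives were fixed before the data were examined. The alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, limma 3.58.1 with voom and quality weights, other sets of libraries in the fit, a replicate block, and leaving out each library in turn. Thinning all libraries to equal totals, taking the shallowest medulla library out of shared fits, leaving out the 10 most abundant genes of the cord, and axis scores as covariates in the cord were added after seeing the data. The axes were the 3 leading principal components of the deviations from group means in 29 libraries, those of the medulla and of the male cord without female hypoxia medulla replicate 3, and every cord library was scored on them. For each comparison, 30 splits of the libraries into groups of the same sizes, the real one included, were fitted in the same way. Standard errors are those implied by the F statistic. A fold against a group at 0 was computed against a floor of 3 counts over the group, which covers counting error only.

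Libraries of the medulla and the cord that share a number come from the same animal by the series design and sample labels. Deviations from group means over all genes correlated positively in 20 of 20 such pairs, at 0.07 to 0.42, and 14 of 20 correlated best with their own number. Over the 100 genes most variable within groups the range was 0.41 to 0.76, and in 20 of 20 animals the medulla library correlated best with the cord library of its own number. The 2 regions of an animal are therefore pairs. The region counts in the results come from fits without a block by animal, as fixed before the data were examined, and the fits with it are given as an alternative. The labels do not say whether the numbers also mark litters.

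On simulated data, drawn from the real means, library sizes and gene-wise dispersions with 100 genes changed 2-fold and 100 changed 1.5-fold, the exposure test in the female cord recovered 59% and 28% of them over 13384 genes. In the male cord the shares were 61% and 29% over 13388 genes. In the medulla they were 44% and 6% in males over 14022 genes, and 29% and 5% in females over 14034 genes. Calls among unchanged genes numbered 3 in the female cord, 9 in the male cord, 4 in the male medulla and 2 in the female medulla. Each gene was drawn independently of the others, so the simulation lacks variation shared across genes. In 29 of the real libraries, 3 axes held 46.5% of the within-group variance. The simulated shares and false calls therefore do not show what to expect in the real libraries. Total counts ran from 6061346 to 24039411 reads per library, and the medulla gave the less precise fold changes, with a median standard error of 0.26 on the log2 scale against 0.18 in the cord.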

Results

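The data describe how microglial transcripts of adult offspring varied with gestational intermittent hypoxia, sex and region of the central nervous system. Each of the 8 groups held 5 libraries, 1 per animal. Total counts averaged 20300000 ± 2500000 reads (SD, n = 5) in the male normoxia medulla and 12300000 ± 1260000 in the male hypoxia medulla. The female medulla groups averaged 13500000 ± 2430000 under normoxia and 13400000 ± 4940000 under hypoxia. In the cord, female hypoxia libraries were the deepest at 17800000 ± 2820000, against 10500000 ± 1920000 in female normoxia, 13200000 ± 2750000 in male normoxia and 10100000 ± 1550000 in male hypoxia. The labels name no sequencing batch. Female hypoxia medulla replicate 3 had the lowest total, 6061346 reads, and counts in 13379 genes, where the other libraries of its group had 17250 to 17850.

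**Figure D1:**
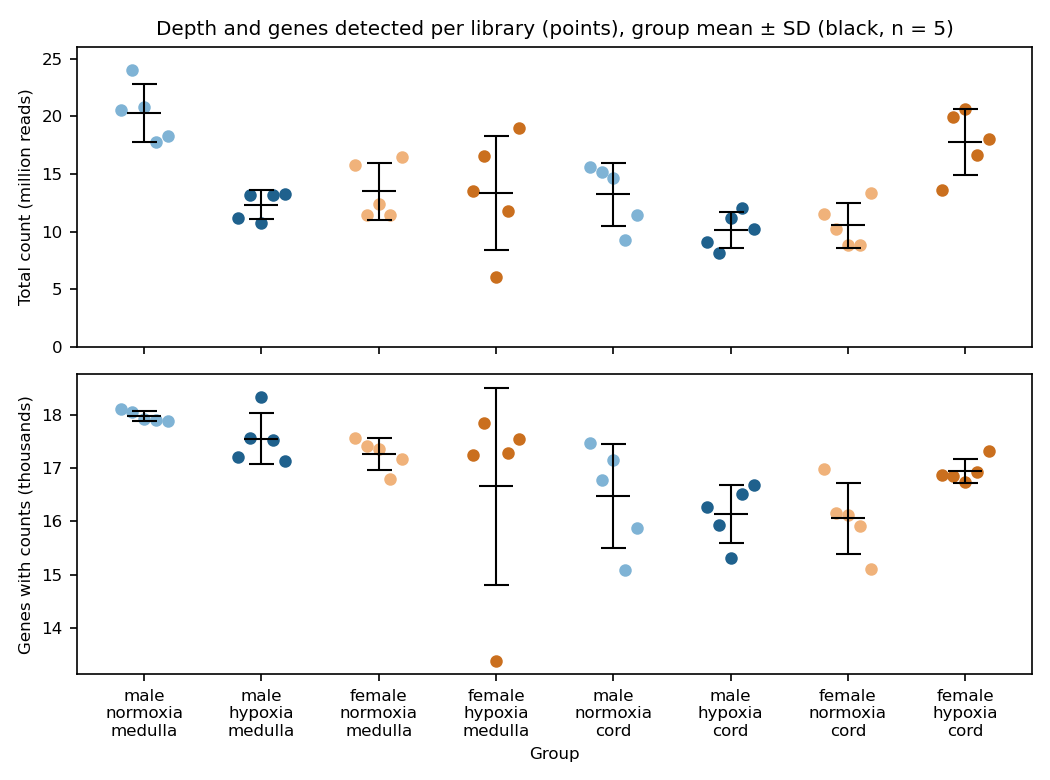
Total read count (top) and number of genes with at least 1 count (bottom) for each of the 40 libraries, by group, with the group mean ± SD in black (n = 5). Female hypoxia medulla replicate 3 lies lowest on both axes, at 6061346 reads and 13379 genes.

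Region and the variation between medulla libraries dominated the expression profiles. The first principal component of log2 CPM, counts scaled to a common library total, carried 30.2% of the variance and the second 13.6%. Cord libraries lay between -8.6 and 56.5 on the first component, while medulla libraries spread from -115.7 to 24.2, leaving aside female hypoxia medulla replicate 3 at 60.4. That library also lay alone on the second component, at 182.3.

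**Figure D2:**
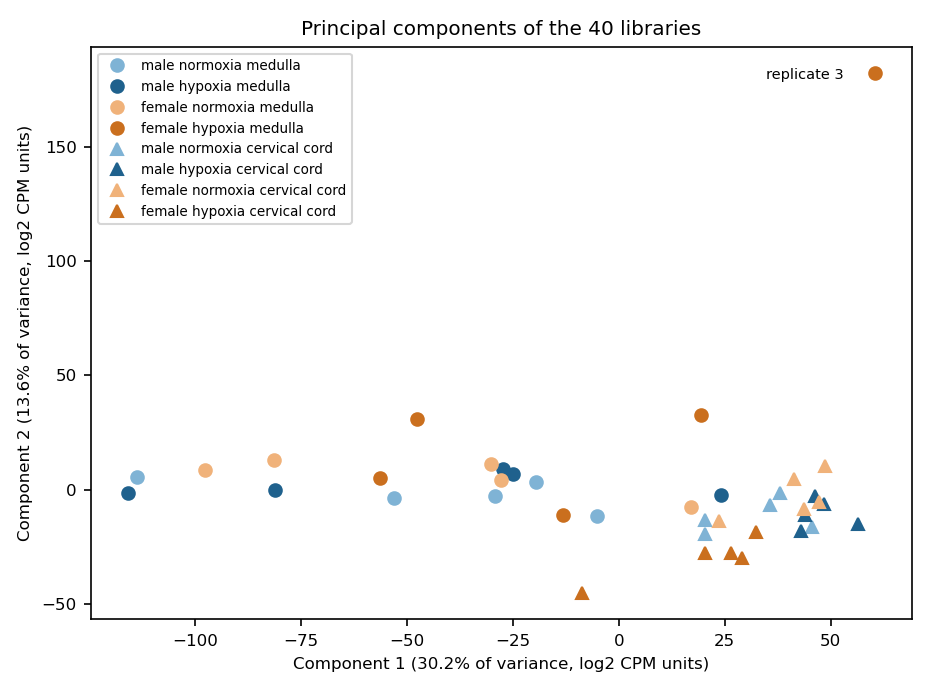
The first and second principal components of log2 CPM for the 40 libraries, in log2 CPM units, with medulla libraries as circles and cord libraries as triangles, coloured by sex and exposure. Cord libraries form a compact set at the right, medulla libraries stretch to -115.7 on the first component, and female hypoxia medulla replicate 3 stands alone at 182.3 on the second.

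The sex labels were compared with the counts through genes picked in the cord alone. In the cord, 9 genes differed over 16-fold between the sexes under both exposures, with no overlap between the libraries of males and females. Of these, 3 were higher in females and 6 in males. In the medulla the 3 genes summed to 314 to 717 CPM in the 10 female libraries and to 0.93 to 3.96 CPM in the 10 male libraries. The 6 genes summed to 240 to 389 CPM in medulla libraries of males and to at most 1.17 CPM in those of females. All 20 medulla libraries thus lay on the side of their label. The condition on overlap was added after the medulla values had been seen; without it 11 genes were picked, 3 higher in females and 8 in males, the 8 summed to up to 184.72 CPM in a female medulla library and to at least 291.05 CPM in those of males, and all 20 libraries again lay on the side of their label.

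The first question was whether microglia of adult offspring differed by gestational exposure, in each sex and region. In the female cervical cord, 4458 of 13593 genes differed between hypoxia and normoxia offspring, 2468 higher and 1990 lower after hypoxia (edgeR quasi-likelihood test, n = 5 per group). These were mostly moderate shifts: the median called gene changed 1.54-fold, and 1087 of the 4458 changed over 2-fold. Calls among genes with an average log2 CPM of 3 to 5 were mostly of higher genes, 1004 against 390 lower, while between 5 and 9 lower genes were more frequent (833 against 817 from 5 to 7, and 392 against 252 from 7 to 9). Relative to the mean of the male cord groups, the median of the 2468 higher genes lay at -0.27 on the log2 scale in normoxia females and at 0.45 in hypoxia females. For the 1990 lower genes these medians were 0.19 and -0.35. The most abundant gene of the table took 6.55 ± 2.72% of the counts in female hypoxia cord libraries (n = 5) and 3.14 ± 0.418% in female normoxia cord libraries. With the groups' totals also apart, at 17800000 and 10500000 reads, depth and exposure moved together in this comparison. With scores on 3 axes of variation taken from the other groups as covariates, 102 genes were called, an alternative added after seeing the data. On the second axis the female normoxia cord libraries scored 0.29 to 1.26 and the female hypoxia cord libraries -2.34 to 0. The score thus parted the groups compared, and the fit cannot tell the axes from the exposure.

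The IDs with the most extreme changes in the female cord varied between animals. ENSRNOG00000057527 averaged 53.2 ± 15.4 CPM (SD, n = 5) in normoxia and 1.61 ± 1.09 CPM in hypoxia, with ranges of 38.2 to 77.6 and 0.833 to 3.52 (log2 fold change -5.03, SE 0.98, edgeR adjusted p = 0.000675). ENSRNOG00000015972 averaged 72.6 ± 64.9 CPM in normoxia, where 3 of 5 libraries held over 20 CPM, and 0.665 ± 0.497 CPM in hypoxia, with high values in the same animals in the medulla (log2 fold change -6.75, SE 1.99, edgeR adjusted p = 0.0127). ENSRNOG00000046081 averaged 23.8 ± 31.4 CPM in hypoxia, where 1 of 5 libraries had no count, and 0.193 ± 0.274 CPM in normoxia (log2 fold change 7.1, SE 2.27, edgeR adjusted p = 0.0204). ENSRNOG00000050156 had no count in any normoxia library and 23.7 ± 30.4 CPM in hypoxia, at least 433-fold higher against the floor of 3 counts over the group (edgeR adjusted p = 0.0284). In the male cord, both rising IDs had their highest values under normoxia. ENSRNOG00000050156 reached 238 CPM in a male normoxia library and at most 12 CPM in male hypoxia libraries. ENSRNOG00000046081 reached 819 CPM in a male normoxia library and at most 76.8 CPM in male hypoxia libraries. Both rising IDs lost their call when single libraries were left out. For ENSRNOG00000050156 the edgeR adjusted p was 0.056 without female normoxia cord replicate 5 and 0.0541 without female hypoxia cord replicate 5. For ENSRNOG00000046081 it was 0.0504 without female normoxia cord replicate 5 and 0.0598 without female hypoxia cord replicate 3. With limma voom and quality weights only ENSRNOG00000057527 among the 4 remained called, with an adjusted p of 0.0203, against 0.243, 0.41 and 0.729 for ENSRNOG00000015972, ENSRNOG00000050156 and ENSRNOG00000046081. With the 3 axis scores as covariates these 3 IDs also lost their call, at edgeR adjusted p values of 0.294, 0.238 and 0.294, while ENSRNOG00000057527 was at 0.0413. The log2 fold changes of ENSRNOG00000015972 and ENSRNOG00000046081 stayed about as large in that fit, at -6.47 and 7.65. Their lost calls thus do not tie these changes to the axes. For ENSRNOG00000050156, read against a group at 0, the fold has no exact value. With all 40 libraries sharing the spread, ENSRNOG00000046081 was at 0.0511.

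**Figure D3:**
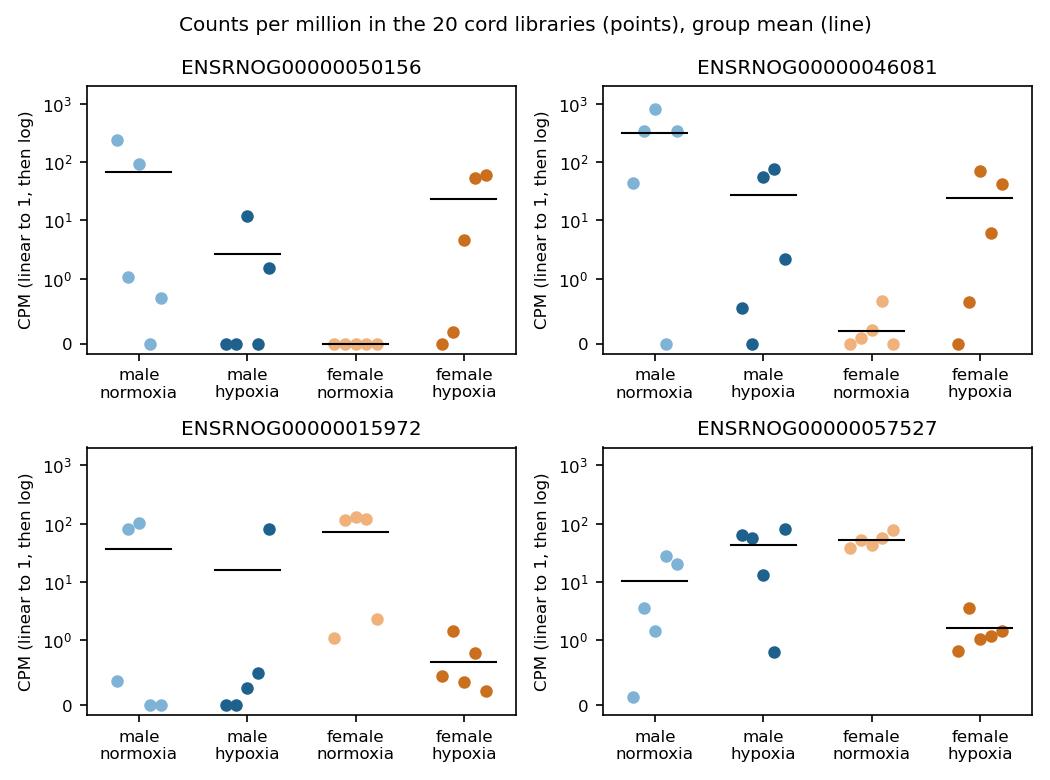
CPM of 4 gene IDs in the 20 cord libraries, by sex and exposure, on an axis that is linear up to 1 and logarithmic above; points are libraries and lines group means (n = 5). ENSRNOG00000057527 reaches 38.2 to 77.6 in female normoxia and 0.833 to 3.52 in female hypoxia. In males it varies more widely, from 0.828 to 81.5 under hypoxia. The other IDs vary widely within some groups, and ENSRNOG00000050156 is at 0 in all 5 female normoxia libraries.

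No gene was called between hypoxia and normoxia offspring in the male cord, the male medulla or the female medulla with edgeR. At an unadjusted p under 0.05 there were 841 genes in the male cord, 122 in the male medulla and 2180 in the female medulla. The 122 were 0.862% of the genes tested, a share below that p threshold itself. With female hypoxia medulla replicate 3 out of the shared fit there were 327, and with only the 10 libraries compared 486. Limma voom with quality weights gave 1507. The 0 calls in the male medulla are thus no evidence that a response was absent. DESeq2 called 1, 0 and 60 genes in these 3 comparisons, and limma voom with quality weights called 0, 0 and 1. In the female medulla, 513 genes passed when all 40 libraries shared the estimate of the spread. Leaving out female hypoxia medulla replicate 3 or female normoxia medulla replicate 5 left 1 called gene in the female medulla, and leaving out male hypoxia cord replicate 5 left 2 in the male cord.

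The exposure difference in the cord was tested for a difference between the sexes. The interaction of sex and exposure called 3155 genes in the cord, 1790 with a more positive and 1365 with a more negative response in females. With the 3 axis scores as covariates the cord interaction called 0 genes, under the same limit that the second score parts the female cord groups. With all 40 libraries sharing the spread the cord interaction called 1562. In the medulla the same interaction called 0 genes with edgeR, 879 had an unadjusted p under 0.05, and DESeq2 and limma voom called 2 and 1. Across 13584 genes, the female and male cord fold changes for hypoxia correlated at -0.24, and of the called female genes 27.9% had the same sign in males. These comparisons share no library, and genes are not independent replicates. The response also differed between the regions in females, where 3078 genes were called in the interaction of region and exposure. In males that interaction called 0 genes with edgeR, DESeq2 and limma voom, and 279 genes had an unadjusted p under 0.05. The 279 were 1.88% of the genes tested, a share below that p threshold, so a difference is not shown to be absent.

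**Figure D4:**
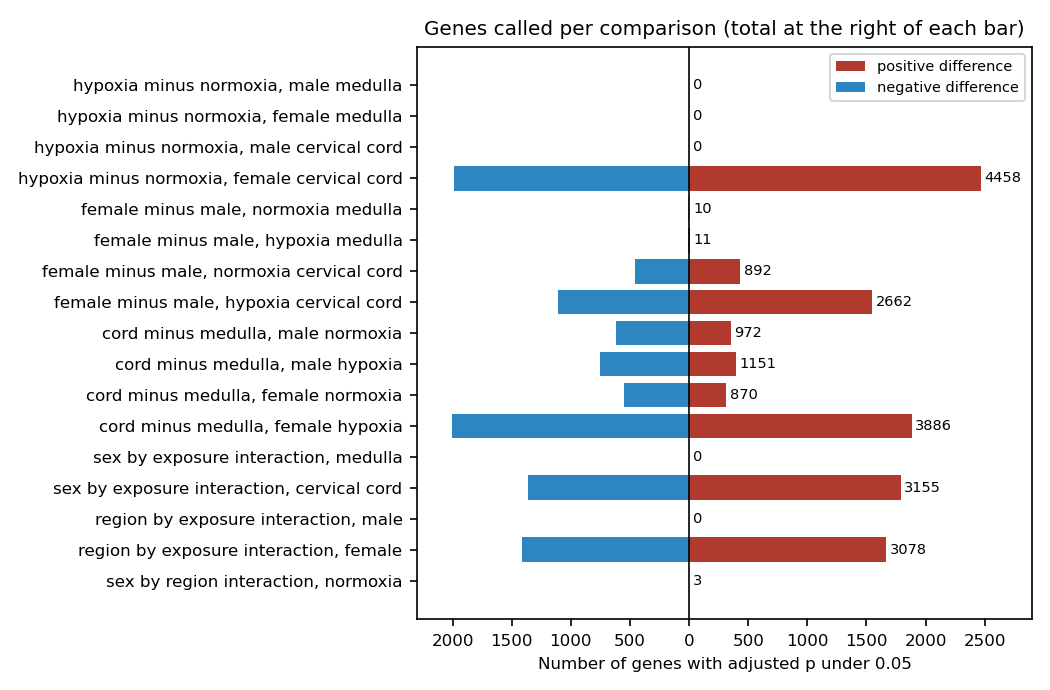
Number of genes with a Benjamini-Hochberg adjusted p under 0.05 in each of the 17 comparisons, with positive differences to the right in red, negative differences to the left in blue and the total beside each bar. The 5 longest bars, from 2662 to 4458 genes, all belong to comparisons that include the female hypoxia cord libraries.

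Genes were called between female and male cord libraries in both exposures. Under normoxia 892 genes were called, 432 higher and 460 lower in females, with a median change of 1.44-fold. Under hypoxia 2662 genes were called, 1551 higher and 1111 lower in females, with a median change of 1.52-fold. The genes of the 2 lists mostly went opposite ways. Leaving aside the 9 genes that differed over 16-fold in every sex comparison, 259 genes were called in both exposures in opposite directions, where independent lists of these sizes would share 86.6. The genes called higher in both numbered 7 (48.9 for independent lists), those called lower in both 3 (36.9 for independent lists), and the fold changes correlated at -0.28 across 13584 genes. The normoxia count moved with single libraries. It was 305, 228 and 386 without male normoxia cord replicates 2, 4 and 5, and 237, 293 and 136 without female normoxia cord replicates 3, 4 and 5. It was 122 when all 40 libraries shared the spread. Other fits raised it, to 1577 with DESeq2 and to 1565 with the replicate number as a block. The labels do not tie that number to a litter. The hypoxia count was 1477 and 1754 without female hypoxia cord replicates 2 and 3, and 992 with all 40 libraries. With the 3 axis scores as covariates, 18 genes were called under normoxia and 23 under hypoxia.

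In the medulla the sexes differed in few genes. Under normoxia 10 genes were called, 3 higher and 7 lower in females, and under hypoxia 11 genes, 4 higher and 7 lower. Of these, 9 were the genes that differed over 16-fold in every sex comparison, which left 1 gene under normoxia and 2 under hypoxia. DESeq2 called 16 and 41 genes, and limma voom with quality weights 26 and 11. With all 40 libraries sharing the spread, 333 genes were called under hypoxia. Whether the sex difference itself differed between the regions was tested under normoxia. There, 3 genes were called, all with a more negative female minus male difference in the cord, and 0 with each animal as a block. Leaving out single libraries gave 0 to 5 genes, and 0 in 8 of the 20 fits.

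Genes were called between cord and medulla libraries within every sex and exposure. No marker gene was checked, so a difference in the cells isolated cannot be told apart from a difference between microglia. In males, 972 genes were called under normoxia, 351 higher and 621 lower in the cord, and 1151 under hypoxia, 399 higher and 752 lower. The excess of lower genes in males depended on the fit. Limma voom with quality weights gave 1045 higher and 963 lower under normoxia and 666 higher and 500 lower under hypoxia, and the 10 libraries compared gave 852 higher and 777 lower under normoxia. In females, 870 genes were called under normoxia, 316 higher and 554 lower in the cord, with a median change of 3.21-fold among called genes. The median changes in males were 2.52-fold and 4.26-fold under normoxia and hypoxia. The normoxia comparisons of males and females, which share no library, had 123 genes called higher in the cord in both (7.48 for independent lists) and 292 called lower in both (23.2 for independent lists), against 2 called in opposite directions. Their fold changes correlated at 0.77 across 14823 genes. In all, 115 genes were higher and 247 lower in the cord in the male normoxia, male hypoxia and female normoxia comparisons together. With female hypoxia as well, 53 were higher and 148 lower in all 4 comparisons, and of the 5071 genes called in any of the 4, 183 were higher in the cord in one comparison and lower in another.

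The leading axis of within-group variation of the female medulla correlated across genes with the male region fold changes at 0.74 under normoxia and 0.73 under hypoxia, in size, while the rank correlations were 0.4 and 0.49. The region counts also depended on single libraries and on the shared spread. Male normoxia gave 291 and 588 genes without medulla replicates 1 and 3, and 565, 487 and 295 without cord replicates 3, 4 and 5. Male hypoxia gave 709 and 386 without medulla replicates 4 and 5, and 728, 662 and 667 without cord replicates 3, 4 and 5. Female normoxia gave 291 and 372 without medulla replicates 1 and 2, and 488, 420, 442 and 478 without cord replicates 2, 3, 4 and 5. With female hypoxia medulla replicate 3 out of the shared fit, the counts were 1937, 1849 and 1812 in male normoxia, male hypoxia and female normoxia. Only the 10 libraries of the groups compared gave 1629, 703 and 1944.

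In hypoxia females, 3886 genes were called between the regions, with 1881 higher and 2005 lower in the cord. With each animal as a block the balance turned, to 2253 higher and 1483 lower. The median change of the 3886 genes was 1.77-fold. Between the normoxia and hypoxia comparisons of females, which share no library, 109 genes were called higher in the cord in both (40.1 for independent lists). Those called lower in both numbered 209 (74.9 for independent lists), and 65 were called in opposite directions (113 for independent lists). Across 14823 genes the fold changes correlated at 0.52, but their rank correlation was -0.01, so the shared direction did not extend over all genes. The count of 3886 fell to 132 genes when only the 10 libraries of the 2 groups set the spread, where the other comparisons gave 703 to 1944. With limma voom and quality weights it was 1712, with 1134 higher and 578 lower, below the 2008 of male normoxia and the 2659 of female normoxia. That this comparison had the highest of the 4 counts thus did not hold in these fits. It did hold with female hypoxia medulla replicate 3 left out, at 3199 genes against 1937, 1849 and 1812 in male normoxia, male hypoxia and female normoxia.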

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

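In this part, the tests of thinned totals and of the region score and second component of the shallowest library, the fits with axis scores, with shuffled axes or without abundant genes, the rank correlations, and the reading of the counts of other splits were chosen after the results they bear on had been seen. The difference between hypoxia and normoxia females in the cord stood apart from that in males, with 3155 genes called in the interaction of sex and exposure, and from that in the medulla, with 3078 genes called in the interaction of region and exposure in females. Of 30 splits of the libraries, only the real one called as many genes in either test, and the highest other split called 63 and 2097. In the comparison of the female cord by exposure the real split called 4458 genes, and the highest of the 29 others called 2206. A share of 1 in 30 is the smallest that 30 splits can give. It makes chance a less likely source of these counts but does not exclude it. The split with 2206 exchanged 1 library of each group, and each of the 23 splits that exchanged 2 called 0.

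The totals of the female cord groups do not account for the 4458 genes, since 4293 were called with every cord library thinned to the smallest total. Nor does the share taken by a few abundant genes, since 4431 were called without the 10 most abundant. Axes of variation that also ran through the other groups may carry much of it, since 102 genes were called with 3 axis scores as covariates, against 142 to 3618 (median 2138) with the axis weights shuffled among genes in 20 draws. The median size of change of the 4458 genes fell from 0.62 to 0.37 on the log2 scale while its median standard error rose from 0.15 to 0.22, so calls ended through both. An effect of the exposure along the same axes would be removed by this adjustment too, and it stays open as an untested explanation, as do cell composition and handling, for which no marker gene or batch label was used here.

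Female hypoxia medulla replicate 3 had 13379 genes with counts, where the others of its group had at least 17250, and a median correlation of 0.86 with its group, where the others had at least 0.935. Its low total is not enough for that, since the other medulla libraries thinned to the same total kept at least 16132 genes. Few RNA molecules behind the library may be the cause, since 118 genes at 0 in it had at least 10 counts in every other thinned medulla library, against at most 4 such genes for any other library in its place. A wrong region label by itself would place it among the cord libraries, yet it lay at 182.3 on the second component, where the 20 cord libraries lay between -45.3 and 10.5. A wrong label beside few RNA molecules stays open, since its score on genes called between the regions in males was 2.04, within the range of female cord libraries (1.43 to 2.56) and above the other female medulla libraries (-0.28 to 1.71). No biological explanation was tested.

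For the genes called between cord and medulla in males, 972 under normoxia, a share of the medulla isolations that varies between libraries and is missing from cord isolations was weighed. The axis was taken from the 9 female medulla libraries alone, and its correlation across genes with the male region fold changes was 0.73 or more in size in both exposures, against at most 0.2 for the axis of the female cord. The correlation thus met the 0.5 set in advance for this explanation. The rank correlations with the medulla axis, added after that result was seen, were lower at 0.4 and 0.49. This explanation may therefore hold, but it is not settled. Library size does not account for the calls, since 836 were left in male normoxia after thinning to equal totals. A difference between microglia of the regions themselves stays open too and was not tested apart from this.

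Among 48 sets of 5 values tested for a single distant sample, 7 were marked where chance gives about 2.4. Male hypoxia cord replicate 2 had 5.25% of its counts in the most abundant gene, where the others of its group had at most 3.76%. Female normoxia cord replicate 3 had a TMM factor of 1.06, where the next was 1.03. Male normoxia cord replicate 4 had a median correlation of 0.952 with its group, where the next was 0.963, and female hypoxia cord replicate 2 had 0.964, where the next was 0.973. ENSRNOG00000057527 stood at 3.52 CPM in female hypoxia cord replicate 2, where the next was 1.47 CPM. The interaction of sex and region under normoxia called 3 genes, and 4 of the 30 splits that swap regions within animals called as many, with up to 309 in another split, so chance is not excluded.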

How the results depend on the processing

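The fits with thinned totals, without the shallowest medulla library, without the 10 most abundant genes and with axis scores were chosen after seeing the data. RLE size factors and thinned totals kept all 17 counts within 1.5 times. The 4458 genes of the female cord by exposure were 3086 to 4834 under every other setting except the axis scores, and 3639 to 4583 with single libraries left out. Where counts moved further, the cause was not tested unless named. DESeq2 called 60 genes in the female medulla and 1 in the male cord by exposure, 16 and 41 by sex in the normoxia and hypoxia medulla, 1577 by sex in the normoxia cord, 1583 and 1459 by region in male and female normoxia, 2 in the medulla interaction of sex and exposure, and 12 in the interaction of sex and region. Limma voom with quality weights called 1 in the female medulla by exposure, 26 by sex in the normoxia medulla, 2008, 2659 and 1712 by region in male normoxia, female normoxia and female hypoxia, and 1 in the medulla interaction of sex and exposure. No filter gave 592 by sex in the normoxia cord, with more genes adjusted for. All 40 libraries gave 513 in the female medulla by exposure, 333, 122 and 992 by sex in the hypoxia medulla, normoxia cord and hypoxia cord, and 1562 in the cord interaction of sex and exposure. Only the 10 libraries compared gave 1629, 703, 1944 and 132 by region in male normoxia, male hypoxia, female normoxia and female hypoxia. Without the shallowest medulla library the first 3 of these were 1937, 1849 and 1812. With axis scores the cord counts were 1 and 102 by exposure in males and females, 18 and 23 by sex in normoxia and hypoxia, and 0 in the interaction.

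With single libraries left out, the counts were 0 to 1 in the female medulla and 0 to 2 in the male cord by exposure, 136 to 1227 and 1477 to 3139 by sex in the normoxia and hypoxia cord, 291 to 1005, 386 to 1305 and 291 to 1110 by region in male normoxia, male hypoxia and female normoxia, and 0 to 5 in the interaction of sex and region. These fits hold fewer samples. No log2 fold change of the 4 IDs changed sign, and for ENSRNOG00000050156 the fit of 10 libraries gave no value because the filter removed it, as for ENSRNOG00000046081.

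The block by animal gave 0 genes in place of 3 in the interaction of sex and region. It kept the other counts by region within 1.5 times, at 1055 and 1216 in male normoxia and hypoxia and 1201 and 3736 in female normoxia and hypoxia, and turned the balance in the last to 2253 higher and 1483 lower. Males and females share only a number, which the labels do not tie to a litter. Deviations of same-numbered libraries correlated at -0.41 to 0.72 over all genes, and 12 of 20 correlated best with their own number. In the cord alone all 10 correlated positively, at 0.06 to 0.35, and 9 of 10 best with their own number, a hint from the data and not from the design. With that number as a replicate block, 1565 genes were called by sex in the normoxia cord. Across exposures 4 of 20 correlated best with their own number, and the block gave 4593 genes in the female cord. The 28 gene lists and their alternatives were not run, since no ID could be paired with a name. In the medulla the wider spread limits what can be detected: the self-test, with genes drawn independently, recovered 6% and 5% of 1.5-fold changes in males and females.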

Other observations

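The tests of genes on in some animals and off in others were chosen after the pattern was seen, and the reading of the counts of other splits after those counts were seen. ENSRNOG00000015972, one of the IDs that fell in the female cord after hypoxia, was high in some animals and nearly absent in others. It stood at 76.3 to 128 CPM in both regions of 6 animals and at no more than 2.34 CPM in both regions of the other 14, with 0 animals differing between regions. Of the 6 animals, 5 were among the 10 of the normoxia group and 1 among the 10 of the hypoxia group. In the cord, 5 genes had every library either at 20 CPM or more or below 2 CPM, with at least 4 animals on each side and no separation by sex. The median such gene was on or off alike in cord and medulla in 100% of animals, and 3 of the 5 matched in all 20 animals. With medulla libraries paired to other animals of the same group in 100 regroupings, the median was 40 to 60%. A property of the animal, such as its genotype in an outbred stock, is a candidate explanation for such genes, so an exposure difference in them may follow which litters fell in which group. Males and females of the same number, which the labels do not tie to a litter, matched in 60% for the median gene.

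Other splits of the libraries were counted for the remaining comparisons, 30 each with the real one. By exposure, the real count was 0 in the male medulla, the female medulla and the male cord, so 30 of 30 splits called as many, and the highest other splits called 0, 390 and 1. The split with 390 in the female medulla points to a structure of those samples. For the interaction of sex and exposure in the medulla and that of region and exposure in males, 30 of 30 splits also called at least the real 0, with 0 as the highest other. By sex, 1 of 30 splits, the real one, reached the 10 genes of the normoxia medulla (highest other 0), the 892 of the normoxia cord (12) and the 2662 of the hypoxia cord (1870). That is the smallest share 30 splits can give, so chance is less likely there but not excluded. In the hypoxia medulla 2 of 30 splits reached the real 11 genes, so the count alone does not exclude chance. Of the 11, 9 differed over 16-fold in every sex comparison. Genes picked in the cord alone also parted the medulla libraries. Those higher in females summed to 314 to 717 CPM in females and 0.93 to 3.96 CPM in males. These values argue against chance for the 9 genes, and chance is not excluded for the other 2. The split with 727 points to a structure of those samples.

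By region, the 2 libraries of an animal are pairs, so the real split was set against the 15 others that also part all 5 pairs. These are too few for a share under 0.05. The real counts were 972 genes in male normoxia, 1151 in male hypoxia, 870 in female normoxia and 3886 in female hypoxia, each reached by 1 of the 16 splits, the real one, and the highest others called 1, 616, 121 and 2417. Each of these highest splits exchanged the regions of 1 animal and left those of 4 as they were. The other 14 splits drawn put both libraries of some animals in the same group, and the highest over all 29 called 1, 616, 245 and 2900.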
